A study of Mus musculus with 2 samples.

How the data were processed

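The series holds droplet single-cell RNA sequencing of colon cells from wild-type C57BL/6 mice. A library of colon cells after Δ9-tetrahydrocannabinol (THC, the main psychoactive cannabinoid of cannabis) at 10 mg/kg was compared with a library of colon cells after vehicle. Per the labels' protocols, the colons were digested in EDTA medium to loosen the epithelium and then with collagenase D, DNAse and Dispase. The lamina propria was enriched on a Percoll gradient, and the cells were loaded on a 10x Genomics Chromium controller with the 5' gene expression kit. How many mice went into a library, their sex and the dosing schedule are not given in the sources used here.

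The deposited matrices hold raw counts of unique molecular identifiers (UMIs, which count RNA molecules) per gene and barcode. Per the file headers, the authors made these counts with Cell Ranger 3.0.2. The submitters' processing notes also name bcl2fastq and Seurat, without versions. The deposited gene and barcode tables hold names of other kinds and no measurement. The genome build and gene annotation are not given in the sources used here, so genes are named by the symbols and identifiers of the files, which list 31053 genes, and no coordinates are printed.

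The deposited counts of the 2 libraries had passed different steps. The THC matrix held all 737280 possible barcodes, of which 106628 had a UMI. The vehicle matrix held 973 barcodes, the lowest with 502 UMIs, so barcodes had been called as cells before deposit. THC barcodes were therefore called as cells when they reached 10% of the 99th percentile of the 3000 largest barcodes, which was 2525 UMIs. Vehicle barcodes needed 500 UMIs. Run on the 973 deposited vehicle barcodes, the rule would give 2890 UMIs. That value is not comparable, since the 99th percentile is then taken over 973 and not 3000 barcodes. THC cells below 2525 UMIs were left out while vehicle cells from 500 UMIs were kept. This bears on every share of cells.

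Cells then needed at least 200 genes and under 10% mitochondrial UMIs. Doublets were marked per library with the scrublet method in scanpy 1.11.5, at an expected 0.8% per 1000 cells, and removed: 1 in the THC and 2 in the vehicle library. A vehicle cell rich in immunoglobulin transcripts was not called a doublet and stayed among the smooth muscle-like cells. These filters left 371 THC and 642 vehicle cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen in each library and combined, without immunoglobulin, T cell receptor, mitochondrial, ribosomal and sex-linked genes. Both libraries were clustered together (30 principal components, 15 neighbours, Leiden resolution 1), which gave 21 clusters.

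Clusters were named from 24 marker lists fixed in advance, of whose 195 genes 193 were in the files. A class is called "X-like" because the names were rebuilt here and are not the authors' annotation. A marker counted for a cluster when at least 10% of the cluster's cells held it and its mean was at least 1 log2 unit above that of all other cells. Among the classes with at least 3 such markers, the class with the highest mean score named the cluster. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when it was shallow and had none of its own markers there. This scoring was written after the data had been seen. It named 10 classes and left 2 clusters unnamed.

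With 1 library per group there were no replicates, so no difference could be compared with the spread between replicates and no test was made. The mice, not the cells, would be the replicates, and no p-value was computed from cells. Shares of cells carry exact binomial 95% intervals. Gene values are log2 ratios of CPM, the share of a gene among the UMIs summed over a class, THC over vehicle, with exact conditional Poisson 95% intervals. These intervals cover counting error alone. They hold neither the variation between mice nor that between preparations. The Poisson intervals also leave out the variation between the cells of a class. They are thus too narrow where 1 cell holds many of a gene's UMIs.

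Single genes were ranked in classes with at least 50 cells in each library, which were the epithelial-like and fibroblast-like classes. A gene could be named with at least 50 UMIs over both libraries in the class, in at least 10% of the class's cells of a library, and with a CPM of at least 20% of its highest class CPM. The last condition guards against free RNA from other classes. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor variable and sex-linked genes were left out. Genes were ranked by the interval bound nearest 0, and the 5 highest and 5 lowest of each class are named, besides members of the fixed lists.

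Fixed before the data were examined were 21 gene lists with 294 genes, all present in the files. They cover cannabinoid receptors and enzymes, MHC class II and class I presentation, interferon-stimulated genes, inflammatory cytokines and chemokines, and type 3 cytokines and regulators. They also cover regulatory T cells and TGF-beta, cytotoxic genes, tissue macrophages, AP-1 and immediate early genes, heat shock and unfolded protein genes, NF-kappaB targets, the cell cycle, and glycolysis and hypoxia. The others are oxidative phosphorylation, cholesterol and lipid synthesis, xenobiotic response, epithelial barrier and antimicrobial genes, germinal centre and B cell activation, plasma cell secretion, and sex-linked genes. The lists were read in the 6 classes with at least 20 cells in each library. A member needed 10 UMIs over both libraries and a list 4 such members. A member with no UMI in a library entered the median at a floor of 3 counts over the class. Each median has an interval from 1000 Poisson draws, for counting error alone, and a percentile among 10000 random lists of as many genes, each drawn from the 100 genes nearest in mean CPM. The percentile describes these 2 libraries and is not a test.

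Shares of cells with a transcript within the T-like, B-like and smooth muscle-like classes were taken after every cell had been thinned to 1000 UMIs, which left out 14 shallower vehicle cells and no THC cell. Shares over all kept cells, and those of cells with Mki67 or Top2a, were taken without thinning. Before the data were examined, 15 alternative settings were chosen, and 3 were added later. They varied the UMI and mitochondrial limits, doublet removal, clustering, scaling, the weight of each cell, depth, the mix of clusters in a class and the cells richest in a gene. No batch is given in the sources used here, and each library is its own preparation, so treatment and preparation cannot be separated.

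The gene ratios and list medians were tested on simulated data with the depth of the real classes. Of genes changed by 1 on the log2 scale, the interval excluded 0 in 93% in the epithelial-like and 88% in the fibroblast-like class. The interval held the true value for 96.0% and 96.1% of unchanged genes. A planted list came out at 1.03 and 0.99 for a true value of 1, and 4% and 3.5% of 200 unchanged lists fell in the outer 2.5% on either side. The simulation holds counting error alone. It drew only genes with at least 50 UMIs, in lists of 15, in the epithelial-like and fibroblast-like classes. Shorter lists, members with fewer UMIs and the smaller classes were not simulated, so these percentages do not cover them.

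The kept cells held 4365813 UMIs in the THC library and 5679147 in the vehicle library. Scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 ran under Python 3.11.15. edgeR 4.0.16 under R 4.3.3 gave the trimmed mean of M values (TMM) scaling, and matplotlib 3.10.9 the plots. Reads were not analysed here. Values of some single list members are not reported here.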

Results

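The study asks how Δ9-tetrahydrocannabinol (THC) bears on the cells of the mouse colon. The compound acts on the cannabinoid receptors Cnr1, found mainly on neurons, and Cnr2, found mainly on immune cells. Kept for comparison were 371 cells of the THC library and 642 cells of the vehicle library, with medians of 9226 and 6913.5 UMIs and of 2803 and 2342.5 genes per cell. Mitochondrial transcripts made up a median of 4.19% and 3.93% of a cell's UMIs, immunoglobulin transcripts 1.2% and 1.81% of all UMIs, and ribosomal protein transcripts 18.3% and 18.5%. The mitochondrial limit removed 190 THC cells (33.8%) and 305 vehicle cells (32.1%). Of the sex-linked genes, Xist, the RNA that silences an X chromosome, had 1268 UMIs in the THC and 2085 in the vehicle library, and its antisense partner Tsix 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 UMIs in both libraries. There was 1 library per group, so the values below describe these 2 libraries, and their intervals cover counting error alone. Genes are given by symbol and, where ranked by the fixed rule, by Ensembl identifier. Positions are not printed, since the build is not given in the sources used here.

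**Figure D1:**
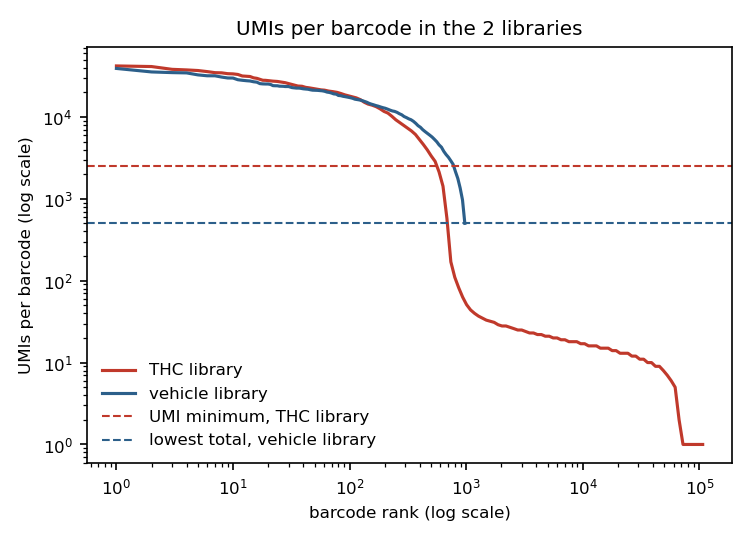
UMIs per barcode (log axis) against the rank of the barcode (log axis) for the THC and the vehicle library. The THC library reached down to barcodes with single UMIs and had a minimum of 2525 UMIs set here, while the vehicle library ended at 502 UMIs, at its 973 called barcodes.

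The colon cells fell into epithelial-like, goblet-like, fibroblast-like, smooth muscle-like, endothelial-like, B-like, T-like, macrophage-like, dendritic-like and plasma-like classes. Fibroblast-like cells were 22.9% of THC cells (95% interval 18.7 to 27.5) and 24.8% of vehicle cells (21.5 to 28.3). Epithelial-like cells were 19.7% (15.8 to 24.1; 73 cells) and 14.2% (11.6 to 17.1; 91 cells), a ratio of 1.39 (1.01 to 1.91). B-like cells, the main lymphocytes here, were 8.63% (5.97 to 12.0) and 11.4% (9.02 to 14.1), a ratio of 0.76 (0.48 to 1.16), and macrophage-like cells 3.50% and 5.61%, a ratio of 0.62 (0.30 to 1.21) that was 1.09 with cells of under 5% mitochondrial UMIs and 1.03 with each library clustered on its own. Goblet-like cells were 12.9% and 12.1%, smooth muscle-like cells 12.4% and 9.66%, T-like cells 6.74% and 6.23%, endothelial-like cells 4.58% and 5.14%, dendritic-like cells 2.43% and 2.65%, and plasma-like cells 1.62% and 1.71%.

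The epithelial-like share held THC cells from 2525 UMIs and vehicle cells from 500. With the low minimum in both libraries it was 20.6% and 18.7%, a ratio of 1.10 (0.82 to 1.47), and 120 in place of 91 of the same 642 vehicle cells took the epithelial-like name. At Leiden resolution 0.5, with the minimums as analysed, 120 vehicle cells took that name too and the ratio was 1.05 (0.78 to 1.42), so the ratio moved with the naming of clusters and not with the minimum alone. It was 1.27 (0.92 to 1.75) with the high minimum in both and 0.73 with each library clustered on its own. Unnamed cells were 4.58% and 6.54%, pooled over 2 clusters that went opposite ways. One held 17 of the 371 THC and 13 of the 642 vehicle cells. The other was a shallow cluster of 29 vehicle cells and no THC cell, led by Gm26917 and histone genes. Of its cells, 25 lay below the THC minimum. With the low minimum in both libraries, all 29 fell in a cluster of 13 THC and 38 vehicle cells.

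**Figure D2:**
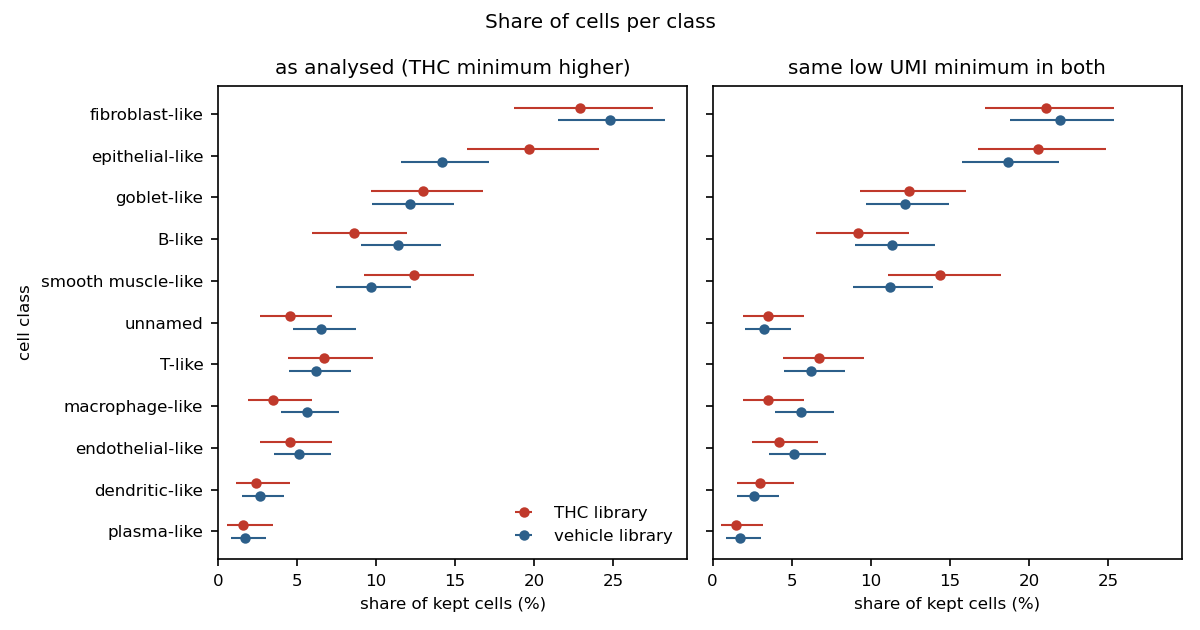
Share of kept cells in each class (percent) in the THC and the vehicle library, with bars for exact binomial 95% intervals, as analysed (left) and with the same low UMI minimum in both libraries (right). The ratio of the epithelial-like shares was 1.39 on the left and 1.10 on the right, where clusters were also found and named anew, so that 120 in place of 91 vehicle cells were epithelial-like.

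In the epithelial-like cells, the genes highest in the THC library were Tgm3 (ENSMUSG00000027401), a transglutaminase that crosslinks proteins, Fabp6 (ENSMUSG00000020405), a bile acid-binding protein, Tac1 (ENSMUSG00000061762), the precursor of substance P, Reg3b (ENSMUSG00000071356), an antimicrobial lectin, and Lgals2 (ENSMUSG00000043501), a galectin. Fabp6 had 1401 UMIs in the THC and 261 in the vehicle library, a log2 ratio of 2.34 (2.15 to 2.54). Tgm3 had 190 and 26 UMIs (2.79; 2.19 to 3.44), Tac1 88 and 11 (2.92; 2.01 to 3.97), Reg3b 384 and 72 (2.33; 1.97 to 2.72) and Lgals2 133 and 40 (1.65; 1.13 to 2.20). Single cells carried much of these counts: 1 THC cell held 77.4% of the Lgals2, 62.2% of the Reg3b, 51.1% of the Tac1 and 34.6% of the Fabp6 UMIs of that library. Without the richest cell of each library, Lgals2 was at -0.21. As the mean of per-cell CPM, Fabp6 was at 0.63, Reg3b at -0.03 and Lgals2 at 0.06. With the high UMI minimum in both libraries, Fabp6 was at 3.85 and Reg3b at 3.81, and with cells of up to 20% mitochondrial UMIs Lgals2 was at 3.05.

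Tgm3 led a cluster of 25 THC and 21 vehicle cells, and Fabp6 and Reg3b led a cluster of 23 and 27 cells. With the same mix of clusters in both libraries, Tgm3 was at 2.36, Fabp6 at 2.13 and Reg3b at 2.13. With cells of up to 20% mitochondrial UMIs, Tgm3 was at 0.74 and Tac1 at -0.51. Tac1 is also a marker of enteroendocrine cells and was at -0.02 with each library clustered on its own.

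Lowest in the THC epithelial-like cells were Cldn14 (ENSMUSG00000047109), a tight junction protein, S100g (ENSMUSG00000040808), a calcium-binding protein, Edn2 (ENSMUSG00000028635), an endothelin peptide, Gm26917 (ENSMUSG00000097971), a non-coding gene model that collects ribosomal RNA reads, and Hspa1a (ENSMUSG00000091971), the inducible Hsp70 chaperone. Edn2 had 189 UMIs in the THC and 442 in the vehicle library (-1.31; -1.56 to -1.06) and Hspa1a 359 and 714 (-1.07; -1.26 to -0.89). Gm26917 had 770 and 1706 (-1.23; -1.35 to -1.10), Cldn14 17 and 98 (-2.61; -3.44 to -1.86) and S100g 16 and 82 (-2.44; -3.31 to -1.65). For Cldn14, 57.1% of the vehicle UMIs came from 1 cell. With cells of up to 20% mitochondrial UMIs, S100g was at 0.02, Edn2 at -0.56 and Cldn14 at -1.50. Gm26917 was at -3.22 at Leiden resolution 0.5 and Hspa1a at -0.42 with cells thinned to 1000 UMIs.

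For each class, the gene lists in the outer 2.5% on either side of matched random lists are given first, and then those inside. In epithelial-like cells, the genes of cholesterol and lipid synthesis were higher in the THC library, with a median log2 ratio of 0.39 (0.27 to 0.58), 14 members higher and 1 lower, above 99.99% of matched random lists. They included Lss (1.42), a sterol cyclase, Insig1 (0.67) and Srebf2 (0.55), which govern sterol synthesis, and Sqle (0.61), a squalene epoxidase. Scd1, a fatty acid desaturase, was at -0.26. The median was 0.72 with each library clustered on its own. The genes of MHC class II presentation, which show peptides to T cells, had a median of 1.81 (1.02 to 2.60) over 4 members, all higher: Cd74 (66 and 24 UMIs; 1.38), Ctss (0.58), H2-Aa (15 and 3 UMIs; 2.24; 0.42 to 4.67) and H2-Eb1 (19 and 1 UMIs; 4.17; 1.51 to 9.54). A single THC cell held 53.3% of the H2-Aa UMIs and a single cell 52.6% of the H2-Eb1 UMIs. The CPM condition against free RNA did not apply to list members, so RNA from other classes was not excluded for these few UMIs. The same list had 13 measured members in B-like cells.

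Interferon-stimulated genes, which act against viruses, had a median of 0.81 (0.30 to 1.48) in epithelial-like cells, with 9 members higher and 3 lower. Isg15 had 56 and 3 UMIs (4.14; 2.52 to 6.46), Ifit1 39 and 5 (2.88) and Rsad2 24 and 6 (1.92), while the chemokine Cxcl10 had 29 and 81 (-1.56). Of the THC UMIs, 1 cell held 85.7% for Isg15 and 89.7% for Ifit1. The median was 0.29 without the cell richest in the list in each library and 0.22 over members with at least 30 UMIs. The barrier and antimicrobial genes had a median of 0.31 (0.26 to 0.61), with 13 members higher and none lower, among them Zg16 (2.03), which binds bacteria, Muc2 (1.36), the main mucin of mucus, with 61.2% of its THC UMIs in 1 cell, the tight junction gene Cldn3 (0.42) and Lypd8 (0.29). Zg16 and Muc2 are markers of goblet cells and led the goblet-like clusters. The barrier median was 0.13 with the same mix of clusters, 0.06 as the mean of per-cell CPM and 0.85 with each library clustered on its own.

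The heat shock and unfolded protein list was at -0.15 (-0.23 to -0.08), lower than all but 0.02% of matched lists, with 6 members higher and 8 lower. Among its members, the chaperone genes Hspa1b (-0.79), Hsph1 (-0.68) and Dnajb1 (-0.43) were lower in the THC library, and Xbp1 (0.62), a regulator of the unfolded protein response, and the chaperone genes Hspa5 (0.54) and Hsp90b1 (0.38) were higher. Thinned to 1000 UMIs the median was 0.01. The germinal centre and activation list was at -0.43 (-0.72 to -0.01) with 1 member higher and 5 lower, among them Myc (-0.58) and Egr2 (-0.31), and at -0.03 with cells of up to 20% mitochondrial UMIs. Inside the outer 2.5% on either side lay 12 lists, among them AP-1 (0.06), NF-kappaB (0.06, and -0.73 with cells thinned to 1000 UMIs), MHC class I (0.02), cell cycle (0.12), glycolysis (0.11, with a mean of the opposite sign at -0.04), oxidative phosphorylation (0.06), xenobiotic response (0.05) and inflammatory genes (0.37, with a mean of -0.01).

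In the fibroblast-like cells, the genes highest in the THC library were Marcksl1 (ENSMUSG00000047945), which binds actin, Procr (ENSMUSG00000027611), the receptor of protein C, Cxcl10 (ENSMUSG00000034855), a chemokine induced by interferon, Adcy5 (ENSMUSG00000022840), an adenylyl cyclase, and Pgf (ENSMUSG00000004791), a growth factor for blood vessels. Cxcl10 had 931 UMIs in the THC and 829 in the vehicle library, a log2 ratio of 0.93 (0.79 to 1.07), and Marcksl1 303 and 173 (1.57; 1.30 to 1.85). Procr had 326 and 245 (1.17; 0.93 to 1.42), Adcy5 38 and 23 (1.49; 0.70 to 2.30) and Pgf 47 and 31 (1.36; 0.68 to 2.06). Procr led a cluster of 14 THC and 20 vehicle cells. It was at 0.83 with the same mix of clusters, 0.25 with the high UMI minimum in both libraries, 0.06 with the low minimum in both, -0.49 with cells of under 5% mitochondrial UMIs and 2.89 with each library clustered on its own. Cxcl10 was found in fewer of the THC cells, without thinning in 34.1% of THC and 39.0% of vehicle fibroblast-like cells. Each of the other genes ranked highest was found in a larger share of the THC cells. Cxcl10 was at 1.62 with cells of under 5% mitochondrial UMIs and 0.59 with cells thinned to 1000 UMIs. Marcksl1 was at 0.94 with each library clustered on its own and 2.28 with cells of under 5% mitochondrial UMIs, and Adcy5 at 3.20 with cells thinned to 1000 UMIs.

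Lowest in the THC fibroblast-like cells were Cxcl13 (ENSMUSG00000023078), which attracts B cells, Pi16 (ENSMUSG00000024011), a marker of adventitial fibroblasts, Il33 (ENSMUSG00000024810), an alarmin cytokine, Ccl7 (ENSMUSG00000035373), which attracts monocytes, and Hspa1a. Hspa1a had 495 UMIs in the THC and 1968 in the vehicle library (-1.23; -1.38 to -1.09) and was 2.35-fold lower. Ccl7 had 206 and 891 (-1.35; -1.58 to -1.13), Pi16 43 and 234 (-1.68; -2.19 to -1.21), Il33 21 and 121 (-1.77; -2.51 to -1.09) and Cxcl13 11 and 219 (-3.55; -4.58 to -2.69). Of the vehicle Cxcl13 UMIs, 56.2% came from 1 cell, and the ratio was -3.01 without the richest cell of each library, -6.40 with the low UMI minimum in both libraries, and -6.37 with up to 20% and -6.24 with under 5% mitochondrial UMIs. Pi16 led a cluster of 23 THC and 47 vehicle cells and was at -1.41 with the same mix of clusters. With each library clustered on its own, Ccl7 was at -5.28, Pi16 at -5.21 and Il33 at -3.59, and Hspa1a at -0.81. Hspa1a was at -0.63 with cells of under 5% mitochondrial UMIs.

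**Figure D3:**
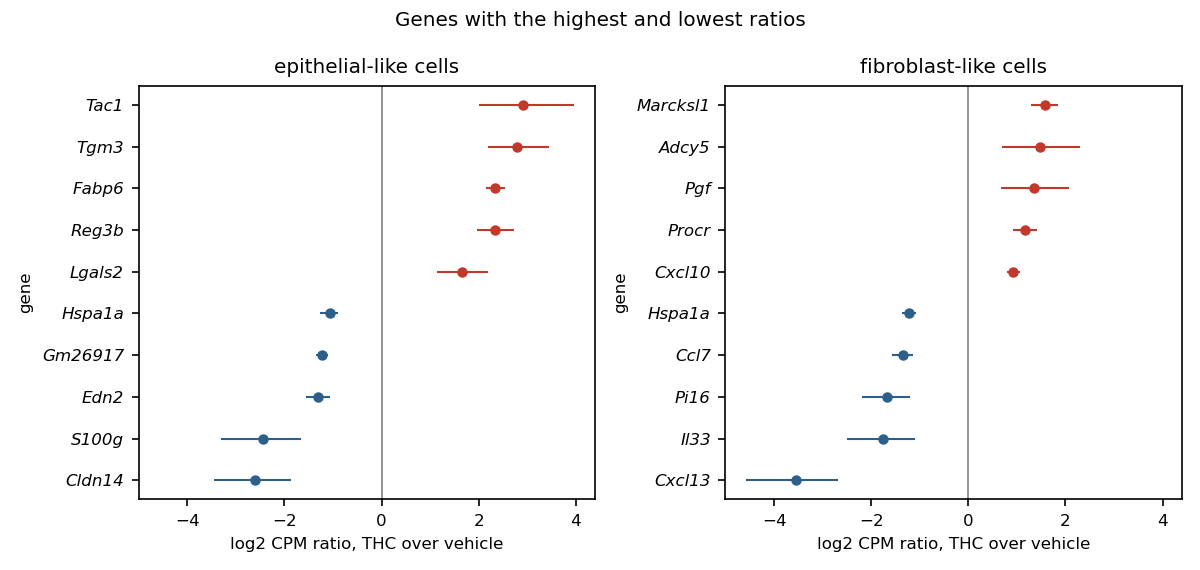
Log2 ratio of CPM, THC over vehicle, of the 5 highest and 5 lowest genes by the fixed rule in epithelial-like (left) and fibroblast-like (right) cells, with bars for exact Poisson 95% intervals of counting error. Hspa1a stands among the lowest in both classes, at -1.07 and -1.23.

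The heat shock list was lower in the THC fibroblast-like cells for all of its 14 members, with a median of -0.37 (-0.54 to -0.27), below all matched random lists. The lowest were the chaperone genes Hsph1 (-1.32), Hspa1a (-1.23), Hspa1b (-1.12), Hspe1 (-0.84) and Hsp90aa1 (-0.82), while Hspa5 was at -0.25 and Hsp90b1 at -0.22. The AP-1 and immediate early genes, which respond within minutes to many stimuli, were higher, with a median of 0.25 (0.19 to 0.29), 14 members higher and 2 lower, among them Fosb (0.39), Dusp1 (0.38), Fos (0.35) and Egr1 (0.32). The heat shock median was -0.58 with each library clustered on its own and -0.22 with cells of under 5% mitochondrial UMIs. The AP-1 median was 0.45 with cells of under 5% mitochondrial UMIs.

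Interferon-stimulated genes in fibroblast-like cells had a median of 0.50 (0.31 to 0.88), with 15 members higher and 2 lower: Cxcl9 had 27 and 4 UMIs (3.52), Ifit3 52 and 22 (2.00), and Gbp2 (1.03), Irf7 (0.98) and Irf1 (0.38) were also higher. Of the THC UMIs, 1 cell held 82.7% for Ifit3 and 59.3% for Cxcl9. The median was 0.26 without the richest cell of each gene and 0.06 with each library clustered on its own. Cholesterol and lipid synthesis genes had a median of 0.57 (0.23 to 0.76), with 11 members higher and 3 lower, among them Hmgcs1 (0.88), Idi1 (0.72) and Srebf2 (0.66). That median was 0.22 with each library clustered on its own and 0.88 with cells thinned to 1000 UMIs.

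Inflammatory cytokines and chemokines were lower in THC fibroblast-like cells, with a median of -0.39 (-0.62 to -0.32), 1 member higher and 7 lower: besides Ccl7, Ccl2 (-0.43), Ptgs2 (-0.34), a cyclooxygenase, and Il6 (-0.24) were lower and the neutrophil attractant Cxcl1 (0.33) higher. Csf2 and Cxcl3 had 0 UMIs in the THC and 15 and 17 in the vehicle library, all 15 of Csf2 in 1 cell, and 1 THC cell held 46.2% of the Ccl2 UMIs. The median was -1.29 with each library clustered on its own and -0.99 without the richest cell of each gene. The plasma cell secretion list was at -0.32 (-0.47 to -0.18) with 1 member higher and 5 lower, among them the unfolded protein genes Creld2 (-0.79) and Xbp1 (-0.42). It shares Xbp1, Pdia4 and Hsp90b1 with the heat shock list, whose members were all lower, so its value is not separate from that list's. The type 3 list was at -0.45 (-1.01 to 0.12), with Il1r1 at -0.74, and at -0.03 with each library clustered on its own. The cell cycle list was at -0.56 (-1.05 to -0.18), with Top2a at 0 and 28 UMIs, all 28 in 1 vehicle cell, and at 0.43 with cells of up to 20% mitochondrial UMIs. Inside the outer 2.5% on either side lay 10 lists, among them MHC class II (0.36, and -0.84 with cells of under 5% mitochondrial UMIs), MHC class I (0.08), NF-kappaB (0.11), glycolysis (0.12), oxidative phosphorylation (0.08), xenobiotic response (0.12), tissue macrophage (-0.03) and regulatory T cell and TGF-beta genes (0.19).

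The smooth muscle-like class held 46 THC and 62 vehicle cells. The median of all measured genes in it was -0.13 and -0.01 with TMM scaling. That shift was not the same at all expression levels, so the percentiles use random lists matched on expression. Medians of these were -0.04 for the heat shock, -0.03 for the interferon-stimulated and -0.001 for the oxidative phosphorylation list. For the regulatory T cell and TGF-beta list the matched median was -0.38. The heat shock list was lower in the THC library, with a median of -0.38 (-0.53 to -0.23), 1 member higher and 13 lower, and -0.25 with TMM: Hspa1b (-1.58), Dnajb1 (-1.10) and Hspa1a (-0.55) were lower. Interferon-stimulated genes had a median of -0.92 (-1.29 to -0.28), or -0.79 with TMM, with 2 members higher and 7 lower, among them Ifi27l2a (-1.22) and Isg15 with 11 and 29 (-1.14). At Leiden resolution 0.5 the interferon median was -0.51.

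In the smooth muscle-like cells, the plasma cell secretion list was at -0.78 (-1.74 to -0.44). That median was -0.05 with cells of under 5% mitochondrial UMIs and -0.41 at Leiden resolution 0.5. A single vehicle cell, which scrublet did not call a doublet, held 99.8% of the 830 vehicle Igkc UMIs, 99.4% of the 336 Igha UMIs and 98.7% of the 318 Jchain UMIs. Oxidative phosphorylation genes were at 0.12 (0.03 to 0.19), with 13 members higher and 3 lower (0.02 with cells thinned to 1000 UMIs and 0.25 with TMM), and MHC class I genes at 0.26 (-0.29 to 0.51), with 5 higher and 4 lower, and at -0.17 with cells of under 5% mitochondrial UMIs. Inside the outer 2.5% on either side lay 11 lists, among them AP-1 (-0.10), cannabinoid (-0.06), tissue macrophage (-0.44) and regulatory T cell and TGF-beta genes (-0.51). The AP-1 median was above 0 under 9 alternative settings, 0.12 with the same mix of clusters.

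**Figure D4:**
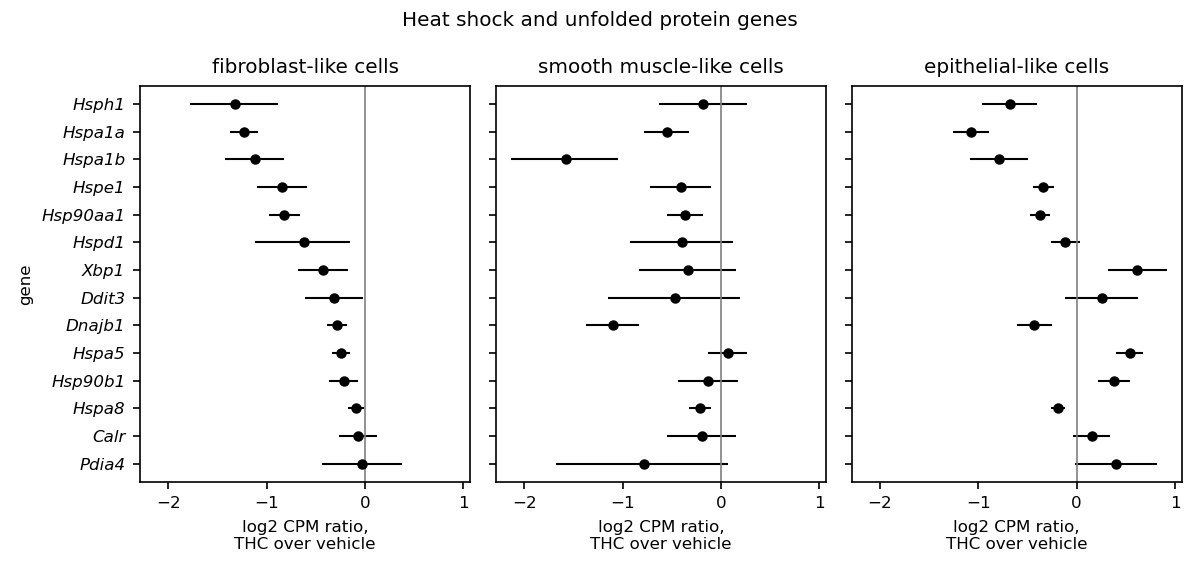
Log2 ratio of CPM, THC over vehicle, of each heat shock and unfolded protein gene in fibroblast-like (left), smooth muscle-like (middle) and epithelial-like (right) cells, with bars for exact Poisson 95% intervals of counting error. In fibroblast-like cells all 14 genes lie below 0, and in epithelial-like cells 6 lie above and 8 below 0.

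The B-like class held 32 THC and 73 vehicle cells. Its cell cycle genes were lower in the THC library, with a median of -1.0 (-1.42 to -0.75), 1 member higher and 16 lower. Mki67, a mark of dividing cells, had 0 and 34 UMIs and Top2a, a DNA topoisomerase of dividing cells, 0 and 30. With the THC count set to the floor of 3, their log2 ratios were -2.18 and -2.0. The floor is a convention, so these values are not limits of the ratios. Stmn1 had 3 and 46 UMIs (-2.62; -4.95 to -0.98) and Tubb5, a tubulin gene, 32 and 172 (-1.11). The germinal centre list was at -0.78 (-1.08 to -0.14), with 3 members higher and 7 lower: Mef2b, a regulator of germinal centre B cells, had 0 and 41 UMIs, and Egr2 2 and 33 (-2.72; -5.83 to -0.76). Without thinning, a UMI of Mki67 or Top2a was found in 7 of 73 vehicle B-like cells (9.59%; 3.94 to 18.8) and in 0 of 32 THC cells. The cell cycle median was -0.59 with cells thinned to 1000 UMIs and the germinal centre median -0.14 over members with at least 30 UMIs.

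The heat shock list in B-like cells was at -0.48 (-0.78 to -0.24), with 3 members higher and 11 lower, among them Hsph1 (-1.44), Hspa1a (-1.25) and Dnajb1 (-1.24), with 64.1% of the THC Hspa1a UMIs in 1 cell, and at -0.81 without the richest cell of each gene. That setting also took the median of all measured B-like genes from -0.06 to -0.23. The plasma cell secretion list was at -0.68 (-0.98 to -0.21), with Jchain at 1 and 36 UMIs (-3.85; -9.19 to -1.28) and Mzb1 at -0.81, and at -0.17 with cells thinned to 1000 UMIs. MHC class II genes were higher, with a median of 0.29 (0.10 to 0.39), 10 members higher and 3 lower, among them Cd74 (0.38), H2-Aa (0.35) and H2-Ab1 (0.43). Among the 7 lists inside the outer 2.5% on either side were interferon-stimulated (0.48), AP-1 (0.17), NF-kappaB (-0.20) and MHC class I genes (0.05, with a mean of -0.18).

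The T-like class held 25 THC and 40 vehicle cells. At Leiden resolution 2, 12 THC and 18 vehicle cells took the name of type 2 innate lymphoid cells instead and 13 and 22 stayed T-like, so the name of these cells depends on the resolution. Its cell cycle genes were higher in the THC library, with a median of 1.13 (0.76 to 2.03), 8 members higher and 1 lower: Stmn1 had 14 and 1 UMIs (4.11; 1.39 to 9.51), Tuba1b 36 and 6 (2.89) and Top2a 11 and 2 (2.76), with 90.9% of the Top2a and 71.4% of the Stmn1 UMIs of the THC library in 1 cell each. The median was 0.42 without the richest cell of each gene and 0.43 with cells thinned to 1000 UMIs, and 2.48 in the cells that stayed T-like at Leiden resolution 2. AP-1 genes were at 0.39 (-0.02 to 0.51), with Jun (1.63) and Fos (0.90) higher and Nfkbia (-1.02) lower, and at 0.11 without the richest cell of each gene and 0.83 at Leiden resolution 2. Interferon-stimulated genes were at -0.91 (-1.41 to -0.31), with Irf1 (-1.12) and Ifi27l2a (-1.70) lower, and at -0.52 as the mean of per-cell CPM. Glycolysis genes were at 0.33 (0.03 to 0.63), and at 0.09 with cells thinned to 1000 UMIs. Inside the outer 2.5% on either side lay 11 lists, among them cytotoxic (0.18; -0.14 to 0.47), regulatory T cell and TGF-beta (-0.21, and 0.21 at Leiden resolution 2), type 3 (-0.29), inflammatory (0.22) and heat shock genes (0.23). The inflammatory median ran from 0.17 to 1.2 over the settings. Hspa1a was higher in THC T-like cells, with 39 and 12 UMIs (2.0; 1.04 to 3.07) and 64.1% of the THC UMIs in 1 cell.

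The goblet-like class, the mucus-secreting epithelium, held 48 THC and 78 vehicle cells. Its cell cycle genes were higher in the THC library for all 17 measured members, with a median of 0.74 (0.46 to 1.14): Top2a had 18 and 3 UMIs (3.04; 1.27 to 5.45), Ccnb2, a cyclin of mitosis, 26 and 6 (2.57), Birc5 20 and 6 (2.19) and Mcm3 15 and 4 (2.36). Barrier and antimicrobial genes were at 0.17 (0.11 to 0.36), with 11 members higher and 2 lower, among them Retnlb (0.79), Zg16 (0.64, with 64.1% of the THC UMIs in 1 cell) and Ang4, an antimicrobial ribonuclease, with 691 and 2 UMIs (8.89; 7.03 to 11.94), of which 1 THC cell held 74.4%. The germinal centre and activation list was at -0.52 (-0.69 to -0.08). The heat shock list lay inside at 0.03, with a mean of -0.13 and with Hspa1b (-0.99) and Hspa1a (-0.90) lower. The cell cycle median was 0.47 with cells of up to 20% mitochondrial UMIs and 1.13 as the mean of per-cell CPM.

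Transcripts of cannabinoid receptors were scarce in both libraries. Over all kept cells, Cnr1 had 1 UMI in the THC and 0 in the vehicle library (0 of 642 unthinned cells with a UMI; 95% interval up to 0.573%, which does not limit expression at this depth), and Cnr2 had 3 and 8 UMIs (0.81% and 1.25% of cells). The related receptors Gpr55 and Gpr18 were found in 3.77% and 3.74% and in 3.50% and 5.30% of unthinned cells, Gpr119 had 1 and 6 UMIs, and the channel Trpv1 had 0 in both. Mgll, the enzyme that degrades the endocannabinoid 2-AG, was found after thinning in 32.6% of THC and 33.9% of vehicle smooth muscle-like cells (84.8% and 85.5% unthinned, at medians of 13121 and 11675.5 UMIs) and in 0 B-like cells of either library (medians of 3260 and 3148 UMIs). The cannabinoid list was at 0.05 in fibroblast-like and -0.07 in epithelial-like cells, inside the outer 2.5% on either side in both.

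Of the type 3 cytokine genes, Il17a and Il17f had 0 UMIs in both libraries, Il22, a cytokine that acts on epithelium, 4 and 1, and Il23r 3 and 2. The regulatory T cell gene Foxp3 had 6 and 9 UMIs and Il10, an anti-inflammatory cytokine, 14 and 19. In T-like cells (medians of 3636 and 3367.5 UMIs) thinned to 1000 UMIs, Icos was found in 28.0% and 30% (44.0% and 57.5% unthinned), Rora in 32.0% and 35.0% (52.0% and 62.5%) and Ctla4 in 4.0% (0.10 to 20.4) and 17.5% (7.34 to 32.8; 12.0% and 30% unthinned). These genes had 0% in thinned B-like cells of both libraries (medians of 3260 and 3148 UMIs).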

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

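The tests of the UMI minimum, the AP-1 genes, Hspa1a across classes and the mix of clusters were chosen after the result was seen, and those of single rich cells and of rare cycling cells before. Among the results set out here, lists stood out because they lay on opposite sides of 0 in different classes, and a gene because it was abundant in barcodes that no comparison uses. The differences between classes were not tested, since there was 1 library per group. Cell cycle genes were at a median of 1.13 in T-like, 0.74 in goblet-like and -1.0 in B-like cells. Interferon-stimulated genes were at 0.81 in epithelial-like, 0.50 in fibroblast-like, -0.91 in T-like and -0.92 in smooth muscle-like cells. In the THC library, 105814 barcodes under 100 UMIs held 817420 UMIs, of which 38.3% belonged to Gm42418, a gene model that overlaps ribosomal RNA. In kept THC cells that share was 2.11%.

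Heat shock genes were lower in THC fibroblast-like cells, at a median of -0.37 with all 14 members lower. The UMI minimum that applied to the THC library alone is argued against, since the median was -0.37 with the same minimum in both. AP-1 genes were higher in the THC cells, at 0.25, which argues against a vehicle dissociation response that raised both lists in fibroblast-like cells. A response that raised heat shock genes without AP-1 genes cannot be decided this way. In smooth muscle-like cells, with heat shock genes at -0.38, AP-1 genes were at -0.10, and from -0.10 to 0.12 over the settings. Hspa1a was lower in 5 of 6 classes and higher in T-like cells, at 2.0 with 64.1% of its THC UMIs in 1 cell, and a difference in temperature or time of handling cannot be told apart from the treatment, because each library is its own preparation. Both stay open.

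Interferon-stimulated genes were higher in THC epithelial-like cells, at 0.81, and in THC fibroblast-like cells, at 0.50. Another mix of clusters within the epithelial-like class is argued against for the value over all cells, with 0.78 at the same mix. That value still holds the richest cell, and the mix was not tested without it. A single cell rich in these transcripts may carry much of the epithelial-like value: without the richest cell of each library the median was 0.29 over 9 measured members in place of 12, above 93.5% of matched lists and so no longer in the outer 2.5%, and the THC cell held 22.2% of the list's THC UMIs. In fibroblast-like cells the same test gave 0.30 against a lower counting bound of 0.31, with 10 members higher and 6 lower, still in the outer 2.5% of matched lists, and the THC cell held 6.54% of the list's THC UMIs, which leaves both readings open. An effect of the treatment on the remaining cells was not tested apart from the preparation.

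Cell cycle genes were lower in THC B-like cells, at -1.0. A UMI of Mki67 or Top2a was found in 9.59% of vehicle B-like cells (7 of 73), and 3 of the 32 THC cells would be 9.38%. That comparison does not give how likely such cells were to be missed. In the THC library 0 of 32 B-like cells had such a UMI, with an interval up to 10.9% that holds the vehicle share. These counts thus neither show nor exclude that too few THC B-like cells left such cells out. The vehicle interval runs from 3.94 to 18.8%, so a true lack of cycling B-like cells in the THC library stays open too, as does a different preparation.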

How the results depend on the processing

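The alternatives were chosen before the data were examined, except the high UMI minimum in both libraries, the same cluster mix and the removal of each gene's top cell, which were chosen after the results were seen. No paired analysis was possible because there was 1 library per group and the results come from no test. Of all values under alternatives, 1597 stayed within the counting interval of their reported value, 174 moved outside it and 27 reversed, meaning that they changed sign where that interval excluded 0. Values whose interval held 0 also changed sign under some settings and stand among the others. The cause was not tested unless the setting itself shows it. Heat shock genes stayed lower in fibroblast-like (-0.58 to -0.22), smooth muscle-like (-0.38 to -0.18) and B-like cells (-0.81 to -0.33), and cholesterol genes higher in epithelial-like (0.27 to 0.72) and fibroblast-like cells (0.22 to 0.88). Kept doublets, a UMI minimum of 1000, Leiden resolution 2 and CPM without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes reversed none in this sense and moved no share of cells and, in epithelial-like and fibroblast-like cells, no list median that lay in the outer 0.5% on either side of matched lists. Kept doublets returned only 1 THC and 2 vehicle cells. With them, and at Leiden resolution 2, the ranked epithelial-like and fibroblast-like genes kept their reported values. Both settings thus tested little in those classes. In B-like cells, kept doublets, Leiden resolutions 0.5 and 2, separate clustering and the same cluster mix all returned the reported list medians. These settings tested nothing for the B-like lists, and the 1597 values include such unchanged ones. Leiden resolution 2 did turn the regulatory T cell list in T-like cells, whose interval held 0. With under 5% mitochondrial UMIs, no cluster took the epithelial-like or goblet-like name, so neither was compared, and with thinning, 30 UMIs per member or separate clustering, some lists lacked 4 members. Depth limits the shares of cells with rare transcripts, which were lower in thinned cells. Values below are log2 ratios of genes and medians of lists.

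The AP-1 list in smooth muscle-like cells, reported at -0.10, reversed to 0.0713 at Leiden resolution 0.5, 0.0274 with TMM, 0.0929 with thinning to 1000 UMIs, 0.0805 with separate clustering, 0.0713 with the low UMI minimum in both, 0.10 as the mean of per-cell CPM, 0.0624 with under 20% and 0.0326 with under 5% mitochondrial UMIs, and 0.12 with the same cluster mix. The AP-1 list in fibroblast-like cells moved to 0.33 with the high and 0.32 with the low UMI minimum in both, 0.16 with separate clustering, 0.16 as the mean of per-cell CPM, 0.32 with under 20% and 0.45 with under 5% mitochondrial UMIs, 0.29 with the same cluster mix and 0.17 without the top cell of each gene. The cell cycle list in fibroblast-like cells, reported at -0.56, reversed to 0.27 with the high and 0.40 with the low UMI minimum in both, 0.28 with separate clustering, and 0.43 with under 20% and 0.36 with under 5% mitochondrial UMIs; most of its vehicle UMIs of Top2a and Mki67 lay in 1 cell.

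Thinning to 1000 UMIs gave, in epithelial-like cells, AP-1 -0.0553, barrier 0.26 and heat shock 0.0071, and in fibroblast-like cells cholesterol 0.88, interferon 0.29 and plasma cell secretion -0.47. Separate clustering gave Tac1 -0.0175, a log2 ratio of epithelial-like shares of -0.46, cholesterol 0.72 and barrier 0.85 in epithelial-like cells, and cholesterol 0.22, heat shock -0.58, inflammatory -1.29 and interferon 0.0639 in fibroblast-like cells; another set of cells carried the names. The mean of per-cell CPM gave, in epithelial-like cells, Reg3b -0.0303, AP-1 -0.0393, barrier 0.0569 and interferon 0.29. Under 20% mitochondrial UMIs gave, in epithelial-like cells, S100g 0.018, Tac1 -0.51, cholesterol 0.27, barrier 0.19, glycolysis -0.0896, heat shock -0.005, inflammatory -0.24 and interferon 0.29. Under 5% gave, in fibroblast-like cells, Procr -0.49 and heat shock -0.22. At least 30 UMIs per member gave epithelial-like interferon 0.22, with fewer members. The same cluster mix gave epithelial-like barrier 0.13 and heat shock -0.0594. Without the top cell of each gene, Lgals2 was at -0.21 in epithelial-like cells, cell cycle at 0.001 in smooth muscle-like cells, and inflammatory at -0.99 and interferon at 0.26 in fibroblast-like cells.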

Other observations

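Transcripts of dividing cells were found in more of the THC goblet-like cells: 13 of 48 (27.1%; 15.3 to 41.8) had a UMI of Mki67 or Top2a, against 6 of 78 vehicle cells (7.69%; 2.88 to 16.0), while 2 of 25 THC and 3 of 40 vehicle T-like cells had such a UMI. This count was made without thinning, at medians of 13977.5 THC and 12229.5 vehicle UMIs per goblet-like cell, and after the list values were seen. Some goblet-like genes, chosen after their values were seen, were carried mostly by single cells. Itln1, an intestinal lectin, had 127 and 3 UMIs (5.86; 4.28 to 8.16), with 93.7% of the THC UMIs in 1 cell, and Clca1, a secreted regulator of mucus, 1366 and 463 (2.02), with 67.5% in 1 cell. Lgals2, whose epithelial-like ratio of 1.65 was -0.21 without the richest cell of each library, had 6 and 95 UMIs in goblet-like cells (-3.53; -5.01 to -2.35), with 74.7% of the vehicle UMIs in 1 cell.

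A cluster of 17 THC and 13 vehicle cells that no marker list named was led by Cidea, Hand1, Clu and Ano1, with Grem1, Nog and Ptger3. Ano1 is a chloride channel known from pacemaker cells of the gut wall and from secretory epithelium, and Grem1 and Nog are secreted antagonists of bone morphogenetic proteins. No marker list for pacemaker cells was fixed, so the cluster carries no name here.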
